A study of Mus musculus with 108 samples.

How the data were processed

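Myeloid cells were purified by flow cytometry from the brains of tumour-bearing and tumour-free athymic nude mice or from their blood, and libraries were made from total RNA, per the labels' protocols. The submitters' processing notes name FastQC, TopHat2 2.0.14, HTSeq, DESeq2 1.18.1 and the genome build GRCm38, without saying which step each was used for. The deposited table gives 1 raw count per gene and library, whole numbers with 49585 genes as rows and 108 libraries as columns, and it was used as deposited. The strand of counting, the annotation release and the read length are not given in the sources used here. Of the gene IDs, 49326 were matched to GENCODE M21 for coordinates on GRCm38, 233 had no symbol and 69 symbols were shared by several IDs. Genes that overlap another gene on the opposite strand may hold its reads, since the strand of counting is unknown.

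Samples were put into 28 groups by title, cell type, tumour stage and radiotherapy field. Tumour-free microglia with titles that carry 5x2 have a radiotherapy field of none and were kept as groups of their own, called titled 5x2. The groups, the 32 comparisons, their tests, the naming of genes and the alternative analyses listed below as chosen beforehand were fixed before the data were examined. Irradiated groups, which carry no stage, were compared with the mean of the unirradiated small and large stages of the same population.

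Statistics were computed with R 4.3.3. For each comparison between groups of a population, all libraries of that population were fitted together, with the tumour-free groups for microglia. Comparisons across populations used the unirradiated groups concerned, and the interaction used the microglia and macrophage groups. Genes were kept by edgeR's filterByExpr at its defaults (minimum count 10, minimum total count 15), scaled by TMM and tested with the quasi-likelihood F-test of edgeR 4.0.16 with 1 mean per group and no covariate. P-values were adjusted over all genes tested in a comparison by Benjamini-Hochberg, with a threshold of 0.0500, and no adjustment was made across comparisons. Standard errors of log2 fold changes come from the same fits, and means and SD are of CPM with TMM factors.

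From general knowledge of these cells, 32 gene lists were drawn up and tested with camera in limma 3.58.1 on log2 CPM, with the preset correlation of 0.0100 and, as a stricter version, with the correlation estimated from the data, each adjusted over the lists of a comparison. A list counts as called on the preset correlation. Where that call was lost with the estimated correlation, the latter's adjusted p is printed beside it, and where it is not printed the call was kept or was absent with both. Members were also counted by the test over all genes and by an adjustment over the list alone. Changes of the p53 target and mitosis lists were compared between populations in 28 interaction tests of the same kind.

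Genes were named by a rule: those past the threshold with the largest log2 fold change in each direction, a mean of 10 CPM or more in the higher group and no overlap between libraries, 10 each way for large-stage against tumour-free microglia, macrophages against microglia, tumour against blood monocytes and 5x2 Gy day 3 of microglia and macrophages, and 5 each way elsewhere, without gene models and immune receptor segments; up to 4 members of each list with the smallest adjusted p; and 14 cell type and response genes anywhere (P2ry12, Tmem119, Sall1, Itga4, Ly6c2, Ccr2, S100a8, Ly6g, Mki67, Cdkn1a, Ifit3, Arg1, Apoe and H2-Aa). Not every gene that the rule allows is printed, and genes with 0 counts in a whole group are mostly left out, since their fold is a lower bound. Phlda3 and Ccng1 are also given in groups where they were not called, for comparison with the groups in which they were, a choice made after their values were seen.

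Alternative analyses chosen beforehand were the scaling factors of DESeq2's method (RLE), no filter on low counts, the Wald test of DESeq2 1.42.0, a block for the replicate number of the titles, a fit of the compared groups alone, the small or the large stage as the reference of irradiated groups, and leaving out each library in turn. Chosen after seeing the data were limma voom with sample quality weights, genes with a mean of 10 CPM or more alone, a term for libraries with a share of ribosomal protein counts 1.5 times their group's median or more (20 libraries), a block for same-numbered libraries in the interaction lists, and leaving out 16 libraries of doubtful quality. A library was of doubtful quality with a total under 3000000 counts, over 30000 genes detected, or over 1% of the population's abundant genes at 0 counts. Figures were drawn with matplotlib 3.10.9, and tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.

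The fits were tested on simulated data, drawn from the means, library sizes and spread of the real libraries with 200 genes changed, 100 by 2-fold and 100 by 4-fold. EdgeR recovered 16% and 79% of them for large-stage against tumour-free microglia (18384 genes), 45% and 79% for macrophages against microglia (14653), 11% and 47% for tumour against blood monocytes (19444), and, for 5x2 Gy day 3, 35% and 68% in microglia (18418), 31% and 70% in macrophages (15452), 21% and 74% in monocytes (14222) and 1% and 30% in granulocytes (13726), with 0 in the wrong direction. In large-stage against tumour-free microglia, edgeR made 4 false calls and DESeq2 39, and in 5x2 Gy day 3 microglia 4 and 30. No other gene was changed, so these rates and false calls may not hold for real libraries with further structure (below). At the median total of 11362593, 1 CPM is 11.4 counts, so genes under 1 CPM rest on few counts, and a fold between means of a few counts has an SE near or above 1. Genes encoded in the mitochondrial genome, at 0 counts in the table, could not be analysed.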

Results

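RNA was counted per gene in 108 libraries of myeloid cells sorted by flow cytometry from athymic nude mice, most of them bearing brain metastases of lung tumour cells. Cells of 4 kinds came from tumour-bearing brains: microglia, the macrophages resident in the brain, monocyte-derived macrophages that entered from the blood, inflammatory monocytes and granulocytes. Each kind was taken without irradiation at the stages the labels call small and large, with 5 and 5 libraries of microglia and of monocyte-derived macrophages and 4 and 5 of monocytes and of granulocytes. Each was also taken after whole-brain radiotherapy, given as 5 fractions of 2 Gy with cells taken on day 3 (4 libraries), day 5 (4) and day 10 (3), or as a single fraction of 10 Gy with cells taken on day 3 (3). The reference cells without tumours were microglia (4 libraries), blood monocytes (4) and microglia with titles that carry 5x2 and day 3 or day 5 (3 each) although their radiotherapy field says none. Total counts per library ran from 985423 to 18642747, with a median of 11362593. The 5 libraries with the fewest counts were control microglia 3 (985423), blood monocytes 1 and 2 (2201047 and 1911008), and monocytes 3 and granulocytes 3 of the 5x2 Gy day 3 groups (1165879 and 1186608). The labels do not say that the libraries of a group came from separate animals, so p-values measure the spread between these samples and not between animals, and they do not say from which event the days are counted. Unless stated otherwise, log2 fold changes are given ± SE, levels are mean CPM (counts scaled to library size) ± SD over the libraries, and adjusted p-values are those of edgeR's quasi-likelihood test or, for gene lists, of camera.

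The sorted cells carried the transcripts by which these cell types are told apart (levels here with TMM factors over all libraries, in the comparisons with those of the libraries fitted together). P2ry12, a purinergic receptor of microglia, was at 2430 ± 1625 CPM in tumour-free microglia and 1418 ± 580 CPM in large-stage microglia, against 297 ± 204 CPM in large-stage monocyte-derived macrophages and 32.8 ± 19.3 CPM in blood monocytes. Sall1, a transcription factor of microglial identity, was at 120 ± 17.0 and 30.9 ± 43.0 CPM in those large-stage groups, the second with 107 CPM in library 5 and 20.9 CPM or less in the others. Ccr2, the receptor by which monocytes leave the marrow, was at 2875 ± 898 CPM in large-stage monocytes and 25.1 ± 36.2 CPM in large-stage microglia. Ly6g, the granulocyte surface marker, was at 74.3 ± 26.4 CPM in large-stage granulocytes and 0.0186 ± 0.0415 CPM in large-stage monocytes, and S100a8, a calcium-binding protein of granulocytes, was at 2356 ± 699 and 47.3 ± 17.4 CPM. Genes encoded in the mitochondrial genome were listed at 0 counts in all 108 libraries, so that RNA quality was not read from them.

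**Figure D1:**
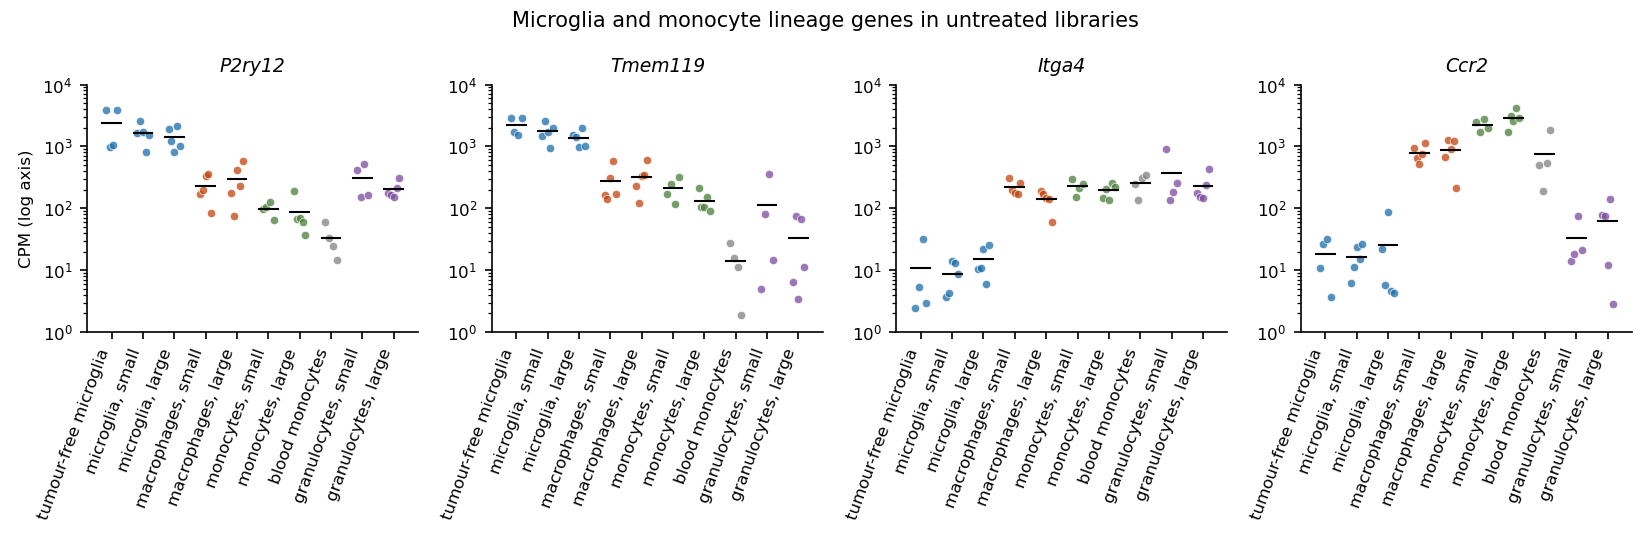
CPM on a logarithmic axis, of 4 lineage genes of microglia or blood-derived cells, in each library of the 10 groups without irradiation and without a title conflict. Points are libraries and the horizontal line is the group mean. P2ry12 and Tmem119 lay highest in the microglia groups, with a mean P2ry12 of 2430 CPM in tumour-free microglia, and Itga4 and Ccr2 in the blood-derived groups, with a mean Ccr2 of 2875 CPM in large-stage monocytes.

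Microglia of tumour-bearing brains were compared with tumour-free microglia to show how resident macrophages differ once metastases are present. At the small stage, disease-associated, interferon-stimulated, inflammatory and complement genes rose. Spp1, which encodes the matrix protein osteopontin (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050), rose from 38.3 ± 25.2 to 3492 ± 2195 CPM (log2 fold change 6.46 ± 0.68, adjusted p = 1.64e-07, 5 against 4 libraries). C3, the central complement component, rose from 1.64 ± 1.13 to 89.5 ± 50.6 CPM (6.19 ± 0.60, adjusted p = 3.42e-08). Cxcl13, a chemokine that attracts B cells, rose from 0.683 ± 1.05 to 948 ± 761 CPM (10.29 ± 2.06, adjusted p = 0.000938). Il12b, the shared subunit of interleukins 12 and 23, and Gbp6, an interferon-induced GTPase, rose by log2 5.99 ± 1.28 and 6.26 ± 0.97. Of the disease-associated microglia genes, known from microglia around plaques, 18 of 23 rose (19 adjusted over the list alone), among them the lysosomal protease Ctsb (1.84 ± 0.15), the protease inhibitor Cst7 (5.80 ± 0.56) and the receptor kinase Axl (3.77 ± 0.40). The list's median was 1.91 (camera adjusted p = 8.39e-18). Of the interferon-stimulated genes, 25 of 29 rose (27 adjusted over the list alone), with Ifit2 (4.08 ± 0.39), Zbp1 (4.34 ± 0.45), Irf7 (4.18 ± 0.45) and Cxcl10 (3.97 ± 0.51) at the smallest adjusted p. The list's median was 2.53 (camera adjusted p = 2.61e-24). Of the inflammatory cytokine and NF-kB genes, 20 of 22 rose (20 adjusted over the list alone), with Tlr2 (2.81 ± 0.28), Nfkbiz (2.17 ± 0.26), Tnf (3.46 ± 0.43) and Il1b (3.52 ± 0.45), and of the complement genes, 10 of 14 rose (11 adjusted over the list alone). Of the immediate early and dissociation genes, which also respond to tissue digestion, 5 of 19 rose (5 adjusted over the list alone), and 7 (7) at the large stage (median 0.47, camera adjusted p = 0.00183, adjusted p = 0.265 with an estimated correlation). Immediate early genes had a median of 0.53 (camera adjusted p = 0.00233, adjusted p = 0.272 with an estimated correlation). The median of inflammatory genes was 2.46 (camera adjusted p = 1.62e-20). Over complement genes the median was 1.45 (camera adjusted p = 9.13e-10).

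Lists of proliferation genes were called in small-stage microglia with the preset correlation alone, and single homeostatic genes fell. Of the mitosis genes, 16 of 23 rose (19 adjusted over the list alone), with Aurka (2.97 ± 0.63), Nusap1 (4.36 ± 0.96), Kif11 (3.73 ± 0.84) and Ccna2 (3.98 ± 0.90), and of the DNA replication genes, 11 of 25 rose (15 adjusted over the list alone). Mitosis genes had a median of 2.97 (camera adjusted p = 3.08e-10, adjusted p = 0.217 with an estimated correlation). The median of DNA replication genes was 1.51 (camera adjusted p = 1.32e-06, adjusted p = 0.272 with an estimated correlation). Of the hypoxia and glycolysis genes, 11 of 21 rose (14 adjusted over the list alone), with Pfkfb3 (1.49 ± 0.23), Pkm (1.97 ± 0.32) and the glucose transporter Slc2a1 (1.31 ± 0.25). The list's median was 1.16 (camera adjusted p = 2.92e-06, adjusted p = 0.125 with an estimated correlation). Of the homeostatic microglia genes, 4 of 19 fell (5 adjusted over the list alone), among them Cst3 (-0.98 ± 0.23), Selplg (-0.87 ± 0.22) and Sall1 (-0.97 ± 0.28), while the list as a whole was not called. Cst3 lost its call without control microglia 3, and Sall1 without control microglia 4 or small-stage microglia 1. Homeostatic genes had a median of -0.43 (camera adjusted p = 0.0504). P2ry12 and Tmem119 did not pass the test, at 1913 ± 638 against 2796 ± 1827 CPM (adjusted p = 0.286) and 2016 ± 623 against 2589 ± 809 CPM (adjusted p = 0.296). Control microglia 2 and 3, of doubtful quality, had 987 and 1059 CPM of P2ry12 and the 2 others 3803 and 3870. Without the libraries of doubtful quality the adjusted p was 0.0672 and 0.267, and Tmem119 passed by DESeq2 (0.0338) and among genes of 10 CPM or more (0.0203). The transcripts that fell most were Npy, Agt, Igfbp5, Igfbp2 and Itih3. Itih3 fell from 136 ± 15.1 to 0.934 ± 0.917 CPM (-7.17 ± 1.27, adjusted p = 0.000225). Agt fell from 39.7 ± 30.0 to 0.126 ± 0.0617 CPM. Astrocyte genes stood higher in the tumour-free libraries: 8 of 10 fell (9 adjusted over the list alone), with a mean log2 CPM over the list of 5.98 ± 0.70 in tumour-free and 2.10 ± 1.01 in small-stage microglia. The median of astrocyte genes was -4.55 (camera adjusted p = 7.4e-11), and whether the named falls reflect astrocyte RNA was not tested. In all, 3035 of 19754 tested genes changed, 1491 higher and 1544 lower. RLE scaling, which moved the median of all genes by -0.19, called 1199 higher and 2333 lower, and 1359 changed without the libraries of doubtful quality and 466 in a fit of the compared groups alone.

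Large-stage microglia were compared with the same 4 tumour-free libraries, so the calls of both stages are not independent. Spp1 was at 5393 ± 2120 CPM (7.08 ± 0.70, adjusted p = 4.52e-08, 5 against 4 libraries), and Cst7 at 421 ± 108 against 5.37 ± 3.65 CPM (6.16 ± 0.56, adjusted p = 1.49e-08). Gpx3, which encodes a secreted glutathione peroxidase, rose from 1.07 ± 0.966 to 258 ± 166 CPM (7.67 ± 1.06). Rab7b, a GTPase of late endosomes, rose from 1.5 ± 0.333 to 103 ± 39.5 CPM (6.17 ± 0.76). Cd5l, a secreted scavenger protein of macrophages, the apolipoprotein gene Apoc4 and the chemokine gene Ccl8 rose by log2 6.91 ± 1.37, 6.41 ± 1.09 and 6.26 ± 1.28. Of the disease-associated genes, 21 of 23 rose (21 adjusted over the list alone), and of the interferon-stimulated genes, 24 of 29 rose (25 adjusted over the list alone). Of the inflammatory genes, 20 of 22 rose (20 adjusted over the list alone), and of the complement genes, 12 of 14 rose (12 adjusted over the list alone). Over disease-associated genes the median was 2.87 (camera adjusted p = 1.68e-19). Interferon-stimulated genes had a median of 2.01 (camera adjusted p = 1.36e-16, adjusted p = 0.0504 with an estimated correlation). The median of inflammatory genes was 2.62 (camera adjusted p = 3.38e-16). Over complement genes the median was 1.99 (camera adjusted p = 1.26e-09). Of the genes of alternative activation and immunosuppression, 8 of 17 rose (8 adjusted over the list alone), with the scavenger receptor Msr1 (5.26 ± 0.72), the folate receptor Folr2 (4.48 ± 0.92) and Il4ra (1.98 ± 0.33), and of the angiogenesis and matrix genes 8 rose and 1 fell (8 and 1 adjusted over the list alone). Alternative activation genes had a median of 1.29 (camera adjusted p = 0.00183, adjusted p = 0.137 with an estimated correlation). The median of angiogenesis and matrix genes was 1.10 (camera adjusted p = 5.24e-05). Among p53 target genes, 11 of 23 rose (12 adjusted over the list alone). Their median was 0.64 (camera adjusted p = 4.28e-05, adjusted p = 0.0511 with an estimated correlation). Of the homeostatic genes, 6 of 19 fell (7 adjusted over the list alone), among them Selplg (-1.22 ± 0.22), Sall1 (-1.35 ± 0.28) and Cst3 (-1.02 ± 0.23), while Fcrls (1.15 ± 0.30) rose. The list's median was -0.70 (camera adjusted p = 0.0366, adjusted p = 0.611 with an estimated correlation).

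The genes with the largest falls at the large stage were at low or scattered levels in the tumour-free libraries. Zfhx4, Tox, Frmpd4, Igsf1 and Grin2b, the last a subunit of the NMDA receptor, fell by log2 estimates between -10.18 ± 2.06 and -8.63 ± 1.92, from 56.6 ± 109, 34.2 ± 65.5, 56.4 ± 108, 26.6 ± 33.6 and 24.5 ± 39.9 CPM in tumour-free microglia. Cntnap5a and Atp6v0a4 fell from 40.5 ± 79.0 and 14.7 ± 27.1 CPM and lost their calls without control microglia 3. Astrocyte genes fell in 7 of 10 cases (8 adjusted over the list alone), neuron genes in 6 of 11 (6) and oligodendrocyte genes in 6 of 11 (6). Control microglia 2 and 3 also held olfactory and vomeronasal receptor genes at 1349 and 9123 CPM. The median of astrocyte genes was -3.86 (camera adjusted p = 1.73e-07, adjusted p = 0.105 with an estimated correlation). Over neuron genes the median was -2.80 (camera adjusted p = 0.0126, adjusted p = 0.353 with an estimated correlation). Oligodendrocyte genes had a median of -2.19 (camera adjusted p = 0.011, adjusted p = 0.265 with an estimated correlation). In all, 6309 of 19754 genes changed, 2315 higher and 3994 lower, and 4110 without control microglia 3, 2955 without the libraries of doubtful quality and 1095 in a fit of the compared groups alone. RLE scaling moved the median of all genes by -0.25 and called 1598 higher and 5217 lower, and among genes of 10 CPM or more 1209 were higher and 1750 lower.

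**Figure D2:**
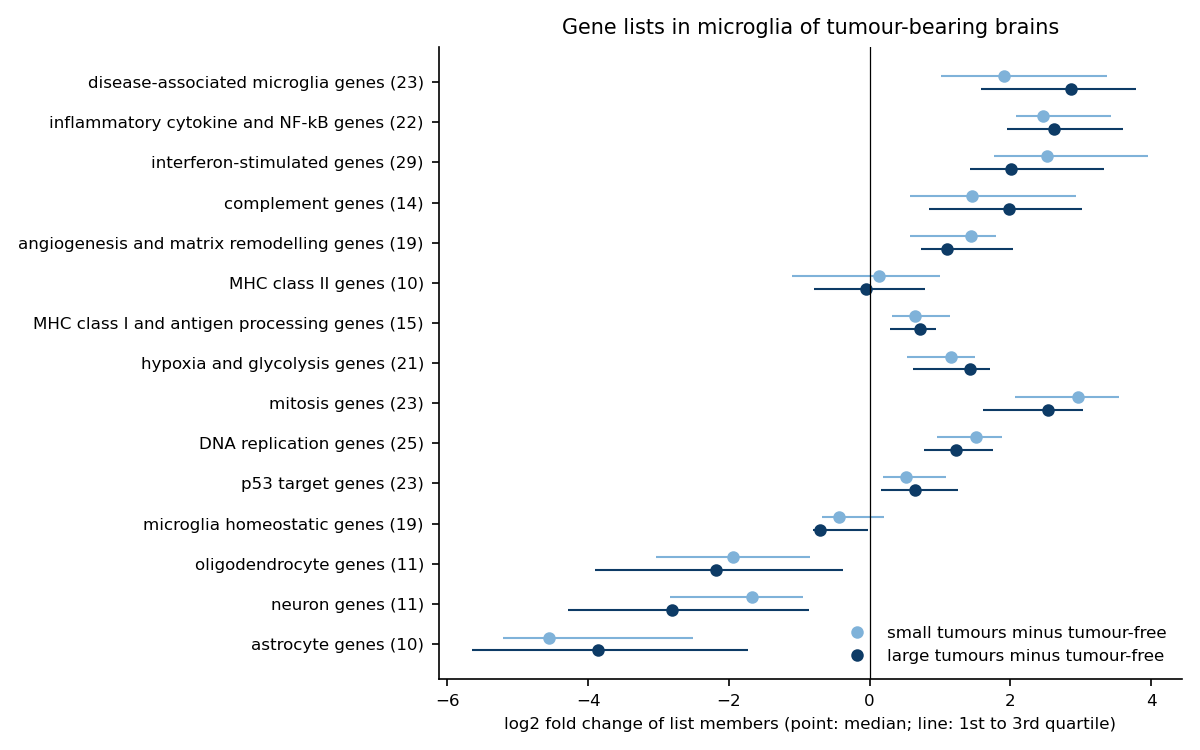
Median log2 fold change of 15 gene lists in small-stage and large-stage microglia against tumour-free microglia (5 and 5 against 4 libraries); points are medians over the measured genes, their number in parentheses, and lines run from the 25th to the 75th percentile of the genes. The disease-associated list had a median of 1.91 at the small and 2.87 at the large stage, and the astrocyte list of -4.55 and -3.86.

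Both macrophage populations of unirradiated tumours were compared (10 against 10 libraries). Antigen presentation and dendritic cell genes were higher in monocyte-derived macrophages. Whether dendritic or B cells in that sort carried them was not tested. Ccr7, the receptor that guides cells to lymph nodes (ENSMUSG00000037944, chromosome 11, 99144196 to 99155077), was at 991 ± 606 CPM against 7.73 ± 6.41 CPM in microglia (log2 fold change 6.99 ± 0.78, adjusted p = 1.16e-06). Ramp3, a modulator of peptide hormone receptors, was at 134 ± 92.6 against 0.970 ± 0.874 CPM (7.14 ± 0.70), and Clec9a, a lectin of cross-presenting dendritic cells, at 32.4 ± 22.8 against 0.292 ± 0.274 CPM (6.95 ± 0.42). All 10 MHC class II genes were higher, with H2-Oa (3.28 ± 0.24), Cd74 (4.24 ± 0.37) and H2-Eb1 (5.00 ± 0.46) (10 adjusted over the list alone). So were 10 of 11 dendritic cell genes, with Itgae (5.28 ± 0.29), Flt3 (5.03 ± 0.38) and Xcr1 (4.58 ± 0.41) (10 adjusted over the list alone). The median of MHC class II genes was 3.66 (camera adjusted p = 5.04e-12). Over dendritic cell genes the median was 5.03 (camera adjusted p = 1.34e-12). Of the monocyte-derived macrophage genes 14 of 15 were higher (14 adjusted over the list alone), among them Itga4, the integrin subunit that separates these cells from microglia (ENSMUSG00000027009, chromosome 2, 79255426 to 79333123), at 201 ± 73.8 against 13.1 ± 7.73 CPM (3.95 ± 0.32, adjusted p = 3.69e-08). The list's median was 4.14 (camera adjusted p = 2.32e-17). Of the alternative activation and immunosuppression genes 12 of 17 were higher (13 adjusted over the list alone), with the haemoglobin scavenger receptor Cd163 (6.26 ± 0.57), the checkpoint ligand Pdcd1lg2 (5.25 ± 0.48) and the chemokine Ccl22 (5.94 ± 0.65), and of the border macrophage genes 9 of 10 (10 adjusted over the list alone). The median of alternative activation genes was 3 (camera adjusted p = 6.55e-07). Over border macrophage genes the median was 3.68 (camera adjusted p = 3.39e-08).

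In the other direction, 18 of 19 homeostatic microglia genes were lower in monocyte-derived macrophages (18 adjusted over the list alone). The list's median was -1.89 (camera adjusted p = 5.04e-12, adjusted p = 0.118 with an estimated correlation). P2ry12 (ENSMUSG00000036353, chromosome 3, 59216272 to 59262871) was at 287 ± 170 CPM against 1696 ± 625 CPM in microglia (-2.57 ± 0.33, adjusted p = 5.53e-06), and Tmem119 at 324 ± 175 against 1719 ± 573 CPM (-2.40 ± 0.28). The fructose transporter gene Slc2a5, the inhibitory receptor gene Lag3 and the adhesion receptor gene Adgrg1 were lower by log2 -4.02 ± 0.52, -3.71 ± 0.44 and -3.21 ± 0.46. Of the complement genes 6 of 13 were lower and 1 higher (7 and 1 adjusted over the list alone), with the integrin subunit Itgam (-1.52 ± 0.18) and C1qc (-0.81 ± 0.19) lower and properdin, Cfp (3.78 ± 0.47), higher. The list's median was -0.46 (camera adjusted p = 0.0292, adjusted p = 0.44 with an estimated correlation). Markers of other cells differed as well: 3 of 4 epithelial genes were higher in monocyte-derived macrophages (3 adjusted over the list alone), with Epcam at 45.1 ± 21.8 against 1.46 ± 1.43 CPM, as were 4 of 8 B cell genes (4). Over epithelial genes the median was 3.48 (camera adjusted p = 0.000401). B cell genes had a median of 2.69 (camera adjusted p = 0.152). In all, 4513 of 15103 genes differed, 2433 higher and 2080 lower in monocyte-derived macrophages.

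Monocytes from unirradiated tumours were compared with monocytes from the blood of tumour-free mice (9 against 4 libraries). Hypoxia, inflammatory and matrix lists were called higher in the tumour with the preset correlation, and each lost its call with an estimated one. Cxcl16, a membrane-bound chemokine and scavenger receptor, was at 544 ± 317 CPM against 13.9 ± 7.87 CPM in blood (log2 fold change 5.27 ± 0.48, adjusted p = 2.06e-07), and Mmp14, a membrane-bound matrix metalloproteinase, at 219 ± 87.0 against 5.05 ± 3.72 CPM (5.45 ± 0.59). Ptgs2, the inducible cyclooxygenase, was at 663 ± 541 against 15.5 ± 7.37 CPM (5.30 ± 0.69). Hal, Cxcl1, Timp1, Il10, Tnfsf9 and Kcnk13 were higher by log2 6.29 ± 0.80, 6.08 ± 1.25, 5.89 ± 0.77, 5.83 ± 1.54, 5.33 ± 0.81 and 5.12 ± 0.59. Of the hypoxia and glycolysis genes 17 of 21 rose (18 adjusted over the list alone), with the hydroxylase subunit P4ha1 (2.38 ± 0.27), Bnip3 (3.33 ± 0.38) and Pfkfb3 (2.82 ± 0.34). The list's median was 1.72 (camera adjusted p = 2.8e-13, adjusted p = 0.0538 with an estimated correlation). Of the inflammatory genes 15 rose and 3 fell among 22 (16 and 3 adjusted over the list alone), with Il1b (3.79 ± 0.39) and Tlr2 (3.11 ± 0.43) higher and Ccl5 (-3.20 ± 0.54) lower. The list's median was 1.84 (camera adjusted p = 6.39e-09, adjusted p = 0.0721 with an estimated correlation). Of the angiogenesis and matrix genes 11 rose and 2 fell among 19 (11 and 2 adjusted over the list alone), and of the complement genes 9 of 14 rose (10 adjusted over the list alone), with the receptors C3ar1 (4.93 ± 0.45) and C5ar1 (2.61 ± 0.36). Angiogenesis and matrix genes had a median of 1.78 (camera adjusted p = 9.38e-07, adjusted p = 0.0538 with an estimated correlation). The median of complement genes was 1.62 (camera adjusted p = 4.51e-08, adjusted p = 0.0538 with an estimated correlation). Of the immediate early and dissociation genes, 14 rose and 1 fell among 19 (14 and 1 adjusted over the list alone), with Ier3 (3.96 ± 0.44), Jun (3.32 ± 0.42) and Hspa1a (5.75 ± 0.82). The list's median was 1.33 (camera adjusted p = 2.74e-11, adjusted p = 0.0538 with an estimated correlation). Tumour effects could not be told from those of tissue digestion, as blood was the reference here and for macrophages below.

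Genes of red cells and lymphocytes were lower in the tumour monocytes than in the blood libraries. Of the erythroid genes 5 of 5 fell (5 adjusted over the list alone), with the haem synthesis enzyme Alas2 at 0.116 ± 0.102 against 359 ± 276 CPM and the globin gene Hbb-bs at 0.764 ± 1.91 against 2268 ± 1400 CPM. The globin genes are near-identical copies, so counts between them are uncertain. Erythroid genes had a median of -11.23 (camera adjusted p = 4.6e-07, adjusted p = 0.0538 with an estimated correlation). Of the T and NK cell genes 10 of 11 fell (10 adjusted over the list alone), with Prf1, the pore-forming perforin, at 2.25 ± 5.01 against 246 ± 236 CPM, and of the B cell genes 8 of 10 fell (8 adjusted over the list alone). The median of T and NK cell genes was -7.47 (camera adjusted p = 0.000126, adjusted p = 0.249 with an estimated correlation). Over B cell genes the median was -5.74 (camera adjusted p = 0.000907, adjusted p = 0.172 with an estimated correlation). In all, 9642 of 21048 genes changed, 2354 higher and 7288 lower, and the median of all genes was -0.65 (-1.07 with RLE scaling). Leaving out blood monocytes 4 gave 14567 calls. Restricted to genes of 10 CPM or more, 1321 were higher and 1396 lower, and each of the 4 blood libraries met a criterion of doubtful quality, such as 37040 genes detected at 1911008 counts in blood monocytes 2.

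Monocyte-derived macrophages of unirradiated tumours were compared with the same blood monocytes (10 against 4 libraries). Ccr7 was at 997 ± 601 against 3.82 ± 4.18 CPM (log2 fold change 8.16 ± 1.43, adjusted p = 0.000363). Fscn1 was at 94.2 ± 58.9 against 0.926 ± 1.08 CPM (7.06 ± 1.25). Ccl22 was at 163 ± 158 against 1.90 ± 1.80 CPM (6.36 ± 1.08) and Cxcl16 at 860 ± 221 against 13.9 ± 7.87 CPM (5.97 ± 0.50). Of the homeostatic microglia genes 16 of 19 rose (16 adjusted over the list alone), with Fcrls (5.20 ± 0.72) and Tmem119 (4.16 ± 0.61). The list's median was 3.30 (camera adjusted p = 1.48e-14). Whether microglial RNA accounts for this was not tested. Of the disease-associated genes 13 rose and 1 fell among 23 (15 and 1 adjusted over the list alone), of the inflammatory genes 17 rose and 1 fell among 22 (17 and 1), and of the alternative activation genes 10 rose and 1 fell among 18 (12 and 1), with the mannose receptor Mrc1 (4.96 ± 0.59) and Stab1 (4.46 ± 0.64) higher. The median of disease-associated genes was 1.76 (camera adjusted p = 9.59e-12). Over inflammatory genes the median was 2.39 (camera adjusted p = 1.23e-13). Alternative activation genes had a median of 2.48 (camera adjusted p = 7.25e-08). All 10 MHC class II genes rose (10 adjusted over the list alone). Their median was 2.13 (camera adjusted p = 9.6e-09, adjusted p = 0.0671 with an estimated correlation). Of the monocyte genes 11 of 12 fell (11 adjusted over the list alone), with Hp (-3.35 ± 0.33), Vcan (-5.23 ± 0.53) and Ly6c2 (-5.07 ± 0.65), and of the neutrophil granule genes 13 of 14 fell (13 adjusted over the list alone). Over monocyte genes the median was -2.67 (camera adjusted p = 7.36e-05, adjusted p = 0.171 with an estimated correlation). Neutrophil granule genes had a median of -4.96 (camera adjusted p = 2.63e-06). Erythroid genes fell in 5 of 5 cases (5 adjusted over the list alone) and T and NK cell genes in 9 of 11 (9). The median of erythroid genes was -11.38 (camera adjusted p = 1.13e-07). Over T and NK cell genes the median was -6.15 (camera adjusted p = 9.78e-05, adjusted p = 0.216 with an estimated correlation). In all, 8336 of 21048 genes changed, 2131 higher and 6205 lower, with 2968, 4966 and 13442 calls without blood monocytes 2, 3 and 4. RLE scaling moved the median of all genes by -0.35, and among genes of 10 CPM or more 1328 were higher and 1399 lower.

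Large-stage cells were compared with small-stage cells of the same kind to show changes during disease progression. In microglia the disease-associated genes lay higher at the large stage as a list, with 0 members called (0 adjusted over the list alone), and the lysosomal gene Cd68 was at 1281 ± 108 against 930 ± 164 CPM (adjusted p = 0.37). The list's median was 0.36 (camera adjusted p = 3.22e-07, adjusted p = 0.241 with an estimated correlation). In monocytes the interferon-stimulated genes lay lower at the large stage, with 0 of 29 called over all genes and 14 adjusted over the list alone. Ifit3 was at 165 ± 59.3 against 462 ± 204 CPM there and Irf7 at 604 ± 130 against 1097 ± 335 CPM. The list's median was -0.71 (camera adjusted p = 1.91e-18, adjusted p = 0.242 with an estimated correlation). In granulocytes the same list lay lower, with 0 of 29 called over all genes and 16 adjusted over the list alone. Ifit3 was at 402 ± 113 against 1596 ± 847 CPM there and Cxcl10 at 21.8 ± 10.1 against 113 ± 83.7 CPM. The list's median was -1.15 (camera adjusted p = 2.24e-20, adjusted p = 0.131 with an estimated correlation). In the same libraries the homeostatic microglia genes lay lower at the large stage, with 0 called over all genes and 5 adjusted over the list alone, and the microglial lectin gene Siglech was at 16.3 ± 9.14 against 296 ± 476 CPM. The list's median was -0.86 (camera adjusted p = 3.62e-07, adjusted p = 0.157 with an estimated correlation). In monocyte-derived macrophages the interferon-stimulated genes lay lower, with 0 called over all genes and 1 adjusted over the list alone, as did the dendritic cell genes, with 0 and 1. The median of interferon-stimulated genes was -0.39 (camera adjusted p = 2.58e-05, adjusted p = 0.712 with an estimated correlation). Over dendritic cell genes the median was -0.93 (camera adjusted p = 0.000104, adjusted p = 0.653 with an estimated correlation). Taken gene by gene, edgeR called 0 genes in microglia, 0 in monocyte-derived macrophages and 0 in monocytes, with 2453, 955 and 568 genes at unadjusted p under 0.05. DESeq2 called 21, 9 and 8, and limma voom with quality weights 0, 0 and 0. In granulocytes 2 genes fell (14 rose and 1639 fell with RLE scaling), of which the naming rule gives Gins2, a replication factor (0.534 ± 0.410 against 88.0 ± 172 CPM, -7.33 ± 1.31, adjusted p = 0.041). Leaving out single libraries gave 0 calls without small-stage granulocytes 1, 380, 293 and 302 without small-stage granulocytes 2, 3 and 4, and 0 without any of the 5 large-stage libraries. In monocyte-derived macrophages 1 gene was called without small-stage library 1 or 4, and in monocytes 1 without large-stage library 5.

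Irradiated microglia were compared with unirradiated microglia of both stages to show the response to whole-brain radiotherapy, and target genes of the transcription factor p53 rose. At 5x2 Gy day 3, Phlda3, which encodes a p53-induced inhibitor of Akt signalling (ENSMUSG00000041801, chromosome 1, 135766119 to 135769136), rose from 1.37 ± 1.02 to 20.9 ± 8.27 CPM (log2 fold change 3.98 ± 0.45, adjusted p = 1.13e-05, 4 against 10 libraries). Cdkn1a, the cell cycle inhibitor p21 (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727), rose from 445 ± 124 to 1435 ± 201 CPM (1.69 ± 0.28, adjusted p = 0.00293). Ccng1, cyclin G1, rose from 138 ± 28.0 to 437 ± 65.7 CPM (1.67 ± 0.23, adjusted p = 0.000299). Inka2, a kinase inhibitor gene, rose from 1.37 ± 0.922 to 17.1 ± 3.23 CPM (3.63 ± 0.49, adjusted p = 0.000292). Map3k20 rose by log2 1.64 ± 0.25. Prune2, Exoc4, Mdm2, Bax and Trpm2 rose by 1.21 ± 0.21, 1.02 ± 0.17, 1.02 ± 0.17, 0.94 ± 0.19 and 0.89 ± 0.18. Of the p53 target genes 5 of 23 rose (13 adjusted over the list alone). Their median was 0.73 (camera adjusted p = 4.87e-53). The mitosis genes lay lower as a list, with 0 of 23 called over all genes and 17 adjusted over the list alone, and Mki67, the proliferation antigen, was at 11.1 ± 9.48 against 41.2 ± 20.8 CPM (adjusted p = 1). The list's median was -1.78 (camera adjusted p = 2.52e-41). In all 12 of 19754 genes rose and 0 fell, and 6 and 6 were called with the small or the large stage as the only reference. Without its library 1, 7 genes rose and Mdm2 and Exoc4 lost their calls, as did Prune2 without library 4. Bax and Trpm2 each lost theirs in 11 of the 14 refits that each left out 1 library.

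In the day 3 group of a single fraction of 10 Gy, 20 genes rose in microglia and 0 fell (3 against 10 libraries). DESeq2, limma voom and a fit of these groups alone called many more. Phlda3 was at 56.0 ± 33.0 CPM (5.40 ± 0.47, adjusted p = 3.25e-08), Ccng1 at 618 ± 160 CPM (2.17 ± 0.25, adjusted p = 7.36e-06) and Inka2 at 25.7 ± 2.57 CPM (4.22 ± 0.52, adjusted p = 1.57e-05). Matn1 rose from 0.431 ± 0.447 to 13 ± 2.54 CPM (4.92 ± 0.62, adjusted p = 2.06e-05). Map3k20 rose from 9.93 ± 3.74 to 45.3 ± 7.81 CPM (2.21 ± 0.27). Among p53 target genes 7 of 23 rose (16 adjusted over the list alone), with Mdm2 (1.45 ± 0.18) and Trp53inp1 (1.91 ± 0.33), and Cdkn1a was at 1464 ± 133 CPM (adjusted p = 0.00396). The list's median was 1.03 (camera adjusted p = 1.25e-36). The mitosis genes were lower as a list, with 0 of 23 called over all genes and 0 adjusted over the list alone. Their median was -0.54 (camera adjusted p = 0.00421, adjusted p = 0.962 with an estimated correlation). Leaving out library 1 of this group gave 10 calls, without Cdkn1a, and library 2 12, without Trp53inp1. With the small or large stage alone as reference there were 12 and 13. At 5x2 Gy day 5, 7 genes rose and 0 fell (4 against 10 libraries), with Phlda3 at 13.8 ± 4.73 CPM (3.38 ± 0.45, adjusted p = 0.00035), Inka2 at 13.8 ± 8.38 CPM (3.32 ± 0.49), Ccng1 at 363 ± 26.8 CPM (1.40 ± 0.23), Cdkn1a at 1204 ± 347 CPM (1.44 ± 0.28, adjusted p = 0.0423) and Map3k20 at 25 ± 3.6 CPM (1.35 ± 0.25). Of the p53 target genes 3 of 23 rose (9 adjusted over the list alone). Their median was 0.62 (camera adjusted p = 1.85e-28). Ccng1 lost its call without library 1 of the day 5 group, where 2 genes were called, and Cdkn1a and Map3k20 each in 11 of 14 refits. The count was 4 without small-stage library 1, 2, 3 or 5 or large-stage library 4, and 3 without small-stage library 4, large-stage library 1 or 2 or day 5 library 2, while with the small or the large stage as the only reference it was 1 and 0. At 5x2 Gy day 10 edgeR called only Phlda3, higher at 14.8 ± 2.81 CPM (3.49 ± 0.47, adjusted p = 0.000619, 3 against 10 libraries). The count was 2 without small-stage library 1 and 0 with the large stage as the only reference. In each 5x2 Gy group DESeq2 and limma voom called more than edgeR (counts below). Among p53 target genes 1 of 23 rose (6 adjusted over the list alone). Their median was 0.54 (camera adjusted p = 5.76e-11). The mitosis and DNA replication genes were higher as lists, with 0 and 0 members called over all genes and 0 and 0 adjusted over the list alone. Mitosis genes had a median of 0.98 (camera adjusted p = 5.5e-12, adjusted p = 0.102 with an estimated correlation). The median of DNA replication genes was 0.90 (camera adjusted p = 9.47e-12, adjusted p = 0.0928 with an estimated correlation). Mki67 was at 77.7 ± 7.72 against 41.2 ± 20.8 CPM (adjusted p = 0.909). Neutrophil and astrocyte genes were higher in the same libraries, with 7 of 15 and 0 of 10 called adjusted over the list alone and 0 and 0 over all genes. Over neutrophil genes the median was 1.58 (camera adjusted p = 1.7e-09, adjusted p = 0.0928 with an estimated correlation). Astrocyte genes had a median of 1.27 (camera adjusted p = 4.12e-10, adjusted p = 0.0928 with an estimated correlation). Gfap was at 70.2 ± 40.9 against 23.0 ± 30.8 CPM.

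**Figure D3:**
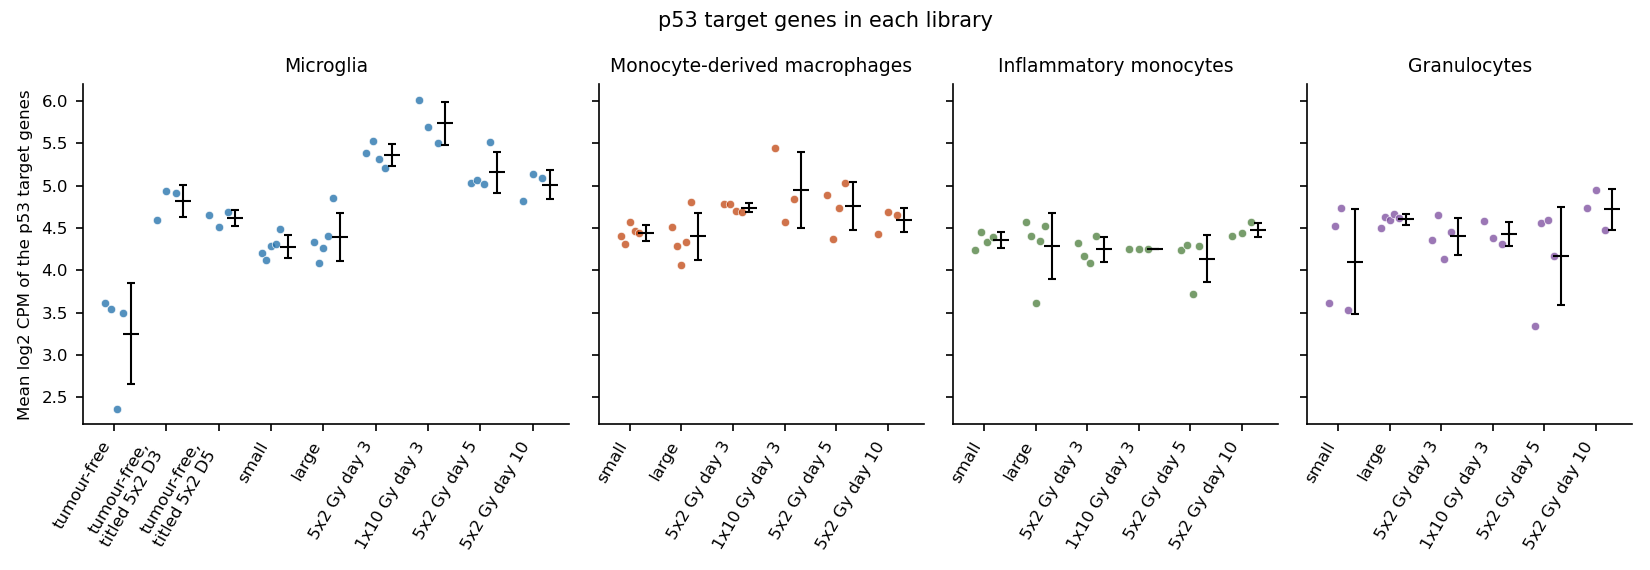
Mean log2 CPM of the p53 target genes in each library, by group, in 4 panels for microglia (with tumour-free groups), monocyte-derived macrophages, monocytes and granulocytes; points are libraries and the bars beside them are the group mean ± SD. The irradiated microglia groups had means of 5.36 ± 0.13, 5.74 ± 0.26, 5.16 ± 0.24 and 5.01 ± 0.17 against 4.28 ± 0.14 and 4.39 ± 0.28 at the unirradiated small and large stages.

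Irradiated monocyte-derived macrophages were compared likewise. After 1x10 Gy Phlda3 rose from 1.46 ± 1.01 to 21.2 ± 16.8 CPM (log2 fold change 3.96 ± 0.57, adjusted p = 0.00821, 3 against 10 libraries), the 1 gene called, and Ccng1 was at 286 ± 111 against 125 ± 24.3 CPM (adjusted p = 0.0596). Of the p53 target genes 1 of 22 rose (6 adjusted over the list alone). The median of p53 target genes was 0.32 (camera adjusted p = 0.000239). At 5x2 Gy day 3, 0 of 22 p53 target genes were called over all genes and 2 adjusted over the list alone. Their median was 0.12 (camera adjusted p = 0.0225, adjusted p = 0.263 with an estimated correlation). Ccng1 was at 242 ± 41.7 against 125 ± 24.3 CPM (adjusted p = 0.744, 4 against 10 libraries). The inflammatory genes lay lower, with 0 called over all genes and 7 adjusted over the list alone. Their median was -0.69 (camera adjusted p = 3.58e-08, adjusted p = 0.263 with an estimated correlation). On day 5, 0 of 22 were called and 2 adjusted over the list alone. The median of p53 target genes was 0.06 (camera adjusted p = 0.0325, adjusted p = 0.312 with an estimated correlation). The dendritic cell and MHC class II genes lay lower on day 5, with 0 of 12 and 0 of 10 called over all genes and 6 and 4 adjusted over the list alone. Over dendritic cell genes the median was -1.19 (camera adjusted p = 1.58e-07, adjusted p = 0.281 with an estimated correlation). MHC class II genes had a median of -0.60 (camera adjusted p = 9.47e-07, adjusted p = 0.312 with an estimated correlation). Flt3 was at 95.3 ± 42.0 against 247 ± 126 CPM (adjusted p = 0.533, 4 against 10 libraries). On day 10 the interferon-stimulated genes lay higher, with 0 of 29 called over all genes and 3 adjusted over the list alone, and C3 was at 224 ± 134 against 82.7 ± 26.7 CPM (adjusted p = 0.407, 3 against 10 libraries). The list's median was 0.47 (camera adjusted p = 3.91e-08, adjusted p = 0.615 with an estimated correlation). EdgeR called 0, 0 and 0 genes on days 3, 5 and 10 of 5x2 Gy, with 930, 1125 and 999 at unadjusted p under 0.05. DESeq2 called 25, 53 and 6, and limma voom with quality weights 1, 0 and 270. After 1x10 Gy both called many more than edgeR (counts below). The call of Phlda3 after 1x10 Gy was lost without library 1 of that group, in a fit of the compared groups alone and with the small or the large stage as the only reference (0, 0, 0 and 0 calls), and 3 genes were called without small-stage library 2. Leaving out small-stage library 1 on day 5, or library 1 or 3 of the day 10 group, gave 1 call each.

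In monocytes and granulocytes after radiotherapy, the lists given here were called with the preset correlation and lost their call with an estimated one, and edgeR called 0 genes in each comparison. At 5x2 Gy day 5 the interferon-stimulated genes lay higher in monocytes, with 0 of 29 called over all genes and 21 adjusted over the list alone. Ifit3, an antiviral effector, was at 745 ± 292 against 297 ± 205 CPM (adjusted p = 0.195, 4 against 9 libraries) and Irf7, a regulator of interferon genes, at 1414 ± 174 against 823 ± 343 CPM. The list's median was 0.74 (camera adjusted p = 8.14e-20, adjusted p = 0.35 with an estimated correlation). After 1x10 Gy the inflammatory genes lay lower in monocytes, with 0 of 22 called over all genes and 0 adjusted over the list alone. Their median was -0.75 (camera adjusted p = 0.000569, adjusted p = 0.647 with an estimated correlation). The same list lay lower in granulocytes after 1x10 Gy, with 0 of 21 called over all genes and 10 adjusted over the list alone, and homeostatic microglia genes lay lower in the same libraries, with 0 of 19 and 6. The median of inflammatory genes was -1.32 (camera adjusted p = 3.91e-06, adjusted p = 0.314 with an estimated correlation). Over homeostatic genes the median was -1.98 (camera adjusted p = 7.85e-06, adjusted p = 0.314 with an estimated correlation). The p53 target gene Phlda3 was at 0.553 ± 0.303 CPM in monocytes and 0.126 ± 0.105 CPM in granulocytes at 5x2 Gy day 3, against 0.293 ± 0.180 and 0.282 ± 0.386 CPM at the unirradiated large stage. The counts of 0 came with 600, 1114, 1475 and 698 genes at unadjusted p under 0.05 in monocytes at 5x2 Gy day 3, day 3 of 1x10 Gy and days 5 and 10 of 5x2 Gy, and 412, 857, 991 and 472 in granulocytes. In the same order DESeq2 called 5, 99, 188 and 34 in monocytes and 2, 128, 180 and 23 in granulocytes, and limma voom with quality weights 439, 1959, 0 and 469 in monocytes and 0 in each of the 4 granulocyte comparisons. Leaving out 1 library gave 10 calls on day 5 without monocytes 2 of that group, and 1 call each without granulocytes 3 of the 1x10 Gy group and of the day 10 group.

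Whether the response differed between the cell populations was tested as the change in the other population minus the change in microglia. At 5x2 Gy day 3 the p53 target genes changed less in monocyte-derived macrophages than in microglia, by a median of -0.70 on the log2 scale (camera adjusted p = 2.17e-12, adjusted p = 5.5e-05 with an estimated correlation), with 0 of 22 called over all genes, 2 adjusted over the list alone and 22 negative. Cdkn1a differed by -1.58 ± 0.30 (adjusted p = 0.329). The same list changed less than in microglia in each of monocyte-derived macrophages, monocytes and granulocytes in all 4 radiotherapy groups, with medians from -1.61 (granulocytes, 1x10 Gy) to -0.44 (monocytes, 5x2 Gy day 10) and adjusted p of 0.000809 or lower over the 28 interaction tests with an estimated correlation. For mitosis genes differences were called with the preset correlation in both directions, 3 up, all at 5x2 Gy day 3 (such as 1.01 in monocytes), and 5 down on days 5 and 10 (such as -1.77 in monocytes on day 10), and 0 with an estimated one (lowest adjusted p = 0.103). Gene by gene, for macrophages at 5x2 Gy day 3, edgeR called 0 of 17247 genes, with 763 at unadjusted p under 0.05, DESeq2 2 and limma voom with quality weights 1, and edgeR 1 without small-stage monocyte-derived macrophages 2. It called 3 and 4 genes for monocytes at 5x2 and 1x10 Gy day 3, and 0 and 0 with same-numbered libraries as a block.

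The day 3 libraries of both schedules were compared to show whether 1 fraction of 10 Gy differs from fractions of 2 Gy. In microglia the p53 target genes lay higher after 1x10 Gy than after 5x2 Gy, with 0 of 23 called over all genes and 0 adjusted over the list alone, and Phlda3 was at 56.0 ± 33.0 against 20.9 ± 8.27 CPM (adjusted p = 0.751, 3 against 4 libraries). P53 target genes had a median of 0.35 (camera adjusted p = 5.35e-05, adjusted p = 0.234 with an estimated correlation). The mitosis genes lay higher as a list, with 0 of 23 called over all genes and 0 adjusted over the list alone, and Mki67 was at 21.0 ± 18.1 against 11.1 ± 9.48 CPM (adjusted p = 0.791). The median of mitosis genes was 1.22 (camera adjusted p = 4.82e-06, adjusted p = 0.68 with an estimated correlation). EdgeR called 0 genes in each of the 4 populations, with 1030 (microglia), 609 (monocyte-derived macrophages), 228 (monocytes) and 265 (granulocytes) at unadjusted p under 0.05. DESeq2 called 34, 1, 0 and 2 and limma voom with quality weights 24, 143, 17 and 0. Without 1x10 Gy microglia 3, edgeR called 2 genes in microglia.

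Tumour-free microglia with titles that carry 5x2 were compared with the other tumour-free microglia by title, since their radiotherapy field says none and the labels do not settle whether they were irradiated. In the group titled day 3, Phlda3 was at 17.1 ± 7.98 CPM against 0.429 ± 0.517 CPM (log2 fold change 5.21 ± 0.76, adjusted p = 0.000847, 3 against 4 libraries) and Cdkn1a at 609 ± 114 against 74.6 ± 37.8 CPM (3.01 ± 0.40, adjusted p = 0.00031). Among p53 target genes 6 of 23 rose (11 adjusted over the list alone), and of the mitosis genes 3 of 23 fell (9 adjusted over the list alone), with Mki67 at 0.234 ± 0.180 against 11.3 ± 11.8 CPM, a call lost without control microglia 3 or titled library 2 or 3. Over p53 target genes the median was 1.22 (camera adjusted p = 1.24e-08). Mitosis genes had a median of -2.30 (camera adjusted p = 2.96e-05, adjusted p = 0.6 with an estimated correlation). In the group titled day 5, Phlda3 was at 20.9 ± 14.3 CPM (5.50 ± 0.77, adjusted p = 0.000495) and Cdkn1a at 900 ± 693 CPM (3.57 ± 0.40, adjusted p = 1.22e-05), and of the p53 target genes 5 of 23 rose (8 adjusted over the list alone). Their median was 0.66 (camera adjusted p = 2.6e-06, adjusted p = 0.0819 with an estimated correlation). The mean log2 CPM of the p53 list was 4.82 ± 0.190 and 4.62 ± 0.0940 (SD, n = 3 each) against 3.25 ± 0.595 (n = 4), higher in each of the 6 titled libraries than in any of the 4 others (two-sided exact permutation p = 0.0286 for either day against the 4 others, the smallest that 35 splits can give). Against the change in tumour-bearing microglia of the same label, no difference of the p53 list was called (median -0.08, adjusted p = 0.319 for day 3, and 0.20, adjusted p = 0.283 for day 5). The mitosis list was called lower on day 5 (median -0.57, adjusted p = 0.0220, 0.609 with an estimated correlation). In all 378 genes changed in the group titled day 3, 163 higher and 215 lower (138 and 536 with RLE scaling). Changes numbered 266 in the group titled day 5, 157 higher and 109 lower (114 and 148). In fits of the compared groups alone the counts were 0 and 0, so Phlda3 and Cdkn1a lost their calls there. Each of the 7 libraries moved these counts by over 1.5 times when left out: 2326, 1106, 30 and 1769 without control microglia 1 to 4 and 169, 4 and 10 without titled libraries 1 to 3 for day 3. For day 5 the counts were 1663, 1429, 33, 896, 146, 60 and 5 in the same order.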

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

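All tests of explanations in this part, and the block, were chosen after the results they weigh were seen, while the comparisons of the p53 response between populations were tests across all 4 radiotherapy groups. Values lay far from the other libraries of their group in 16 of 72 checks of totals, genes detected, ribosomal protein share and p53 list level, where chance gives about 1 in 20 groups, or 3.6 here. The total of small-stage granulocytes 1 was 3805740 (others 10291326 to 11275704) and that of large-stage microglia 5 was 18099551 (others 9375942 to 11550543), and large-stage macrophages 2 had 31357 genes detected (others 16300 to 20045). The mean log2 CPM of the p53 list was 2.36 in control microglia 3 (others 3.49 to 3.61), 3.62 in large-stage monocytes 3 (others 4.34 to 4.58), 5.52 in 5x2 Gy day 5 microglia 4 (others 5.01 to 5.07) and 3.72 in 5x2 Gy day 5 monocytes 3 (others 4.24 to 4.3). No explanation was tested for these.

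The share of counts in ribosomal protein genes was 0.251% in control microglia 1 (others 0.458 to 0.494) and stood above its group in 8 libraries: 0.853% in small-stage microglia 3 (others 0.225 to 0.378), 0.837% in large-stage microglia 5 (others 0.311 to 0.415), 0.938% in large-stage macrophages 5 (others 0.417 to 0.536), 1.067% in large-stage monocytes 5 (others 0.288 to 0.459), 0.967% in 5x2 Gy day 3 macrophages 4 (others 0.365 to 0.451), 0.204% in 5x2 Gy day 3 granulocytes 4 (others 0.076 to 0.096), 1.043% in 5x2 Gy day 5 microglia 4 (others 0.265 to 0.334) and 1.062% in 5x2 Gy day 5 macrophages 4 (others 0.383 to 0.445). By a wider rule, 1.5 times the group's median or more, 20 libraries were high, and in 3 of 4 stages or treatments with such a library in all 4 populations these carry the same number, which may come from a shared animal or library batch, and the labels name neither. Lower depth is argued against, since the median ratio of the totals of those 20 to their group's median was 1.2. The biological explanation, a difference between animals, was not tested and stays open.

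The p53 target genes changed less after radiotherapy than in microglia, a difference between populations, with medians of -0.699 in macrophages, -1.076 in monocytes and -1.074 in granulocytes at 5x2 Gy day 3, -0.911, -1.585 and -1.615 at 1x10 Gy day 3, -0.499, -0.851 and -1.096 at 5x2 Gy day 5 and -0.458, -0.437 and -0.538 at 5x2 Gy day 10. Each passed its test with an estimated correlation, at an adjusted p of 0.000809 or lower over 28 tests. These contrasts share microglia libraries, so they are not independent. With same-numbered libraries of 2 populations as a block, 12 of 12 were called with an estimated correlation (adjusted p of 0.00595 or lower). No explanation of the difference was tested.

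In tumour-free microglia titled 5x2, the p53 target genes stood higher than in the other tumour-free microglia. Every titled library lay above every other, with a gap of 0.903 in mean log2 CPM between the lowest titled and the highest other library, which may reflect radiotherapy as the titles say, against the radiotherapy field. The 2 control libraries of doubtful quality, 2 and 3, do not account for it, since the difference from control microglia 1 and 4 alone was 1.165, against an SD of 0.190 or less within the titled groups. A difference in handling or day between the titled and the other groups was not tested, since the labels give neither.

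Genes lower in tumour than in blood monocytes included 354 of the 372 tested olfactory and vomeronasal receptor genes, with 1 higher, which are not expected in these cells. For genes under 10 CPM, background reads in the blood libraries could thus account for lower calls. For abundant genes this stays open, as does a biological difference between blood and tumour, since the share of lower calls there, 51.4%, is held near an even split by the scaling and decides nothing.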

How the results depend on the processing

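Limma voom, abundant genes alone, the ribosomal protein term, the interaction block and omitting doubtful libraries were chosen after seeing the data. Of 156 values of named genes under 3308 alternatives, 3119 kept their side of the threshold, 151 lost their call and 38 gained one. Among values called in the main or alternative fit, 0 reversed direction. Calls of lists numbered 354 of 986 tests, of which 36 were kept with an estimated correlation. Counts of genes that moved by over 1.5 times are given by alternative, and for these the cause was not tested except where fewer genes or libraries were used. DESeq2 called 2379 for microglia titled 5x2 day 3, 2046 for microglia titled 5x2 day 5 and 2 for the interaction, in microglia 21 for large against small stage, 27 at 5x2 Gy day 3, 169 at 1x10 Gy day 3, 36 at 5x2 Gy day 5, 58 at 5x2 Gy day 10 and 34 for 1x10 against 5x2 Gy, in macrophages 9 for large against small stage, 25 at 5x2 Gy day 3, 64 at 1x10 Gy day 3, 53 at 5x2 Gy day 5, 6 at 5x2 Gy day 10 and 1 for 1x10 against 5x2 Gy, in monocytes 8 for large against small stage, 5 at 5x2 Gy day 3, 99 at 1x10 Gy day 3, 188 at 5x2 Gy day 5 and 34 at 5x2 Gy day 10, and in granulocytes 695 for large against small stage, 2 at 5x2 Gy day 3, 128 at 1x10 Gy day 3, 180 at 5x2 Gy day 5, 23 at 5x2 Gy day 10 and 2 for 1x10 against 5x2 Gy. Limma voom with quality weights called 1231 for small-stage against tumour-free microglia, 2794 for large-stage against tumour-free microglia, 13556 for macrophages against blood and 1 for the interaction, in microglia 33 at 5x2 Gy day 3, 1715 at 1x10 Gy day 3, 56 at 5x2 Gy day 5, 413 at 5x2 Gy day 10 and 24 for 1x10 against 5x2 Gy, in macrophages 1 at 5x2 Gy day 3, 535 at 1x10 Gy day 3, 270 at 5x2 Gy day 10 and 143 for 1x10 against 5x2 Gy, in monocytes 439 at 5x2 Gy day 3, 1959 at 1x10 Gy day 3, 469 at 5x2 Gy day 10 and 17 for 1x10 against 5x2 Gy, and in granulocytes 0 for large against small stage. Without a filter on low counts edgeR called 23914 for monocytes against blood, 21619 for macrophages against blood, 743 for microglia titled 5x2 day 3 and 451 for microglia titled 5x2 day 5, in microglia 11 at 5x2 Gy day 5 and 4 at 5x2 Gy day 10, in macrophages 1 for large against small stage, 12 at 5x2 Gy day 3, 6 at 1x10 Gy day 3, 24 at 5x2 Gy day 5, 14 at 5x2 Gy day 10 and 1 for 1x10 against 5x2 Gy, in monocytes 158 for large against small stage, 18 at 5x2 Gy day 3, 60 at 1x10 Gy day 3, 171 at 5x2 Gy day 5, 42 at 5x2 Gy day 10 and 7 for 1x10 against 5x2 Gy, and in granulocytes 331 for large against small stage, 42 at 5x2 Gy day 3, 74 at 1x10 Gy day 3, 218 at 5x2 Gy day 5, 48 at 5x2 Gy day 10 and 17 for 1x10 against 5x2 Gy. Fits of the compared groups alone, with fewer libraries, called 466 for small-stage against tumour-free microglia, 1095 for large-stage against tumour-free microglia, 0 for microglia titled 5x2 day 3 and 0 for microglia titled 5x2 day 5, in microglia 98 at 1x10 Gy day 3, in macrophages 0 at 1x10 Gy day 3, in monocytes 1 at 1x10 Gy day 3, and in granulocytes 0 for large against small stage. Abundant genes alone gave 2959 for large-stage against tumour-free microglia, 2717 for monocytes against blood and 2727 for macrophages against blood, in microglia 13 at 1x10 Gy day 3, in macrophages 0 at 1x10 Gy day 3, and in granulocytes 0 for large against small stage. RLE scaling gave 674 for microglia titled 5x2 day 3, and in granulocytes 1653 for large against small stage. It also moved the median of all genes by -0.22, -0.28 and -0.21 in granulocytes at 5x2 Gy day 3, 1x10 Gy day 3 and 5x2 Gy day 5, -0.20 for their stages (14 genes higher and 1639 lower) and -0.17 and -0.10 for microglia titled day 3 and day 5. The ribosomal protein term gave 753 for microglia titled 5x2 day 3 and 722 for microglia titled 5x2 day 5, in macrophages 3 at 1x10 Gy day 3, and in granulocytes 0 for large against small stage. Without libraries of doubtful quality there were 1359 for small-stage against tumour-free microglia, 2955 for large-stage against tumour-free microglia, 89 for microglia titled 5x2 day 3 and 530 for microglia titled 5x2 day 5, in microglia 4 at 5x2 Gy day 10, in monocytes 3 at 1x10 Gy day 3, and in granulocytes 0 for large against small stage, and the comparisons with blood could not be made, since each blood library was doubtful. With the small stage as the reference there were in microglia 6 at 5x2 Gy day 3, 12 at 1x10 Gy day 3 and 1 at 5x2 Gy day 5, and in macrophages 0 at 1x10 Gy day 3 and 2 at 5x2 Gy day 5, and with the large stage in microglia 6 at 5x2 Gy day 3, 13 at 1x10 Gy day 3, 0 at 5x2 Gy day 5 and 0 at 5x2 Gy day 10, in macrophages 0 at 1x10 Gy day 3, and in monocytes 15 at 5x2 Gy day 5. Leaving out each library in turn gave ranges of 4110 to 7178 for large-stage against tumour-free microglia, 6562 to 14567 for monocytes against blood, 2968 to 13442 for macrophages against blood, 4 to 2326 for microglia titled 5x2 day 3, 5 to 1663 for microglia titled 5x2 day 5 and 0 to 1 for the interaction, in microglia 7 to 13 at 5x2 Gy day 3, 10 to 20 at 1x10 Gy day 3, 2 to 10 at 5x2 Gy day 5, 1 to 2 at 5x2 Gy day 10 and 0 to 2 for 1x10 against 5x2 Gy, in macrophages 0 to 1 for large against small stage, 0 to 3 at 1x10 Gy day 3, 0 to 1 at 5x2 Gy day 5 and 0 to 1 at 5x2 Gy day 10, in monocytes 0 to 1 for large against small stage and 0 to 10 at 5x2 Gy day 5, and in granulocytes 0 to 380 for large against small stage, 0 to 1 at 1x10 Gy day 3 and 0 to 1 at 5x2 Gy day 10.

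Within populations the replicate numbers of the titles do not pair the samples: 2 of 81 pairs of groups had every same-numbered correlation of deviations over 0.1 (the titled groups with each other, and titled day 5 with large-stage microglia), with 95 of 273 samples best with their own number. Between populations same-numbered libraries deviated together more often, in 21 of 36, with 105 of 139 samples best with their own, among them microglia and macrophages at 5x2 Gy days 3, 5 and 10, but not those of the small stage (lowest -0.405) or of the large stage. With a replicate block the counts moved to 1979 for small-stage against tumour-free microglia, 3878 for large-stage against tumour-free microglia, 10 for microglia titled 5x2 day 3 and 26 for microglia titled 5x2 day 5, in microglia 3 at 5x2 Gy day 5, in macrophages 0 at 1x10 Gy day 3, in monocytes 1 for large against small stage, 12 at 1x10 Gy day 3 and 12 at 5x2 Gy day 10, and in granulocytes 0 for large against small stage and 1 at 1x10 Gy day 3. Depth and spread limit what can be called: on simulated data at the depths and spread of the real libraries, edgeR recovered 1% of 2-fold and 30% of 4-fold changes in granulocytes at 5x2 Gy day 3, so that counts of 0 there leave changes of that size open.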

Other observations

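Of the tests in this part, those of the small-stage microglia and of the microglia titled 5x2 day 3 were chosen after their results were seen, and the others before. Libraries were split anew within each comparison, and a split was counted by the side on which each library falls, a rule set after an early count had taken a shuffle of the stages among tumour monocytes for another split. No other drawn split gave as many genes for large-stage against tumour-free microglia (1 of 50 splits, real 6309, highest other 3145). Nor did any for macrophages against microglia (1 of 50, 4513, 2) or macrophages against blood (1 of 50, 8336, 7). For monocytes against blood (1 of 50, 9642, 8994) the highest other split came close, with blood monocytes 4 on the tumour side. The real split is among the 50, so 1 of 50 is the lowest share possible, and no adjustment was made across comparisons. Such counts do not speak to single genes or lists. Other splits gave as many for small-stage against tumour-free microglia (4 of 50 splits, real 3035, highest other 5419), so chance was not excluded. This was so too for large against small stage in granulocytes (6 of 50, 2, 57). In microglia the same held at 5x2 Gy day 3 (3 of 50, 12, 3026) and 1x10 Gy day 3 (4 of 50, 20, 2764). It also held there on day 5 (5 of 50, 7, 1661) and day 10 (7 of 50, 1, 1) of 5x2 Gy. In macrophages it held at 1x10 Gy day 3 (11 of 50, 1, 97). For microglia titled 5x2 it held for day 3 (10 of 35, 378, 3504) and day 5 (10 of 35, 266, 5206). With a real count of 0 by edgeR (counts at unadjusted p under 0.05 and by other tools are in the report), every split gives as many, 35 of 35 for 1x10 against 5x2 Gy and 50 of 50 elsewhere, and the highest other is 1593 for the interaction, in microglia 1 for large against small stage and 1 for 1x10 against 5x2 Gy, in macrophages 133 for large against small stage, 219 at 5x2 Gy day 3, 396 at 5x2 Gy day 5, 5 at 5x2 Gy day 10 and 0 for 1x10 against 5x2 Gy, in monocytes 1 for large against small stage, 0 at 5x2 Gy day 3, 6 at 1x10 Gy day 3, 592 at 5x2 Gy day 5, 18 at 5x2 Gy day 10 and 0 for 1x10 against 5x2 Gy, and in granulocytes 532 at 5x2 Gy day 3, 856 at 1x10 Gy day 3, 993 at 5x2 Gy day 5, 1318 at 5x2 Gy day 10 and 0 for 1x10 against 5x2 Gy. Splits with several times the real count point to a structure of the samples that the groups do not follow. For small-stage against tumour-free microglia, the highest other split put the 4 libraries of doubtful quality on 1 side and the 5 others on the other, and without the libraries of doubtful quality the real split called 1359. In microglia at 5x2 Gy day 3, 1x10 Gy day 3 and 5x2 Gy day 5, the highest other splits each set small-stage microglia 1 and 4, of doubtful quality, on 1 side. Small-stage granulocytes 1, of doubtful quality, stood on the smaller side of the highest splits of all 4 radiotherapy groups of granulocytes, and control microglia 2 and 3 stood together in those of both titled groups. In macrophages at 5x2 Gy day 3 and day 5 and in monocytes on day 5, the highest split put all 3 compared libraries with a high ribosomal protein share together, and with a term for that share edgeR called 0, 0 and 0 genes.

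Olfactory and vomeronasal receptor genes together reached 15470 CPM in blood monocytes 2, 9123 CPM in control microglia 3 and 1299 CPM in small-stage microglia 4. Of 162 pairs of libraries within groups, 0 were identical.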
